A study of Mus musculus with 12 samples.

How the data were processed

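Total RNA from the liver of night-fed male Cry1/Cry2 double-knockout mice was sequenced as stranded, rRNA-depleted, paired-end libraries, per the labels' protocols. The authors deposited raw exon counts per gene, whole numbers without normalization, in 1 table. Alignment with STAR 2.4.0i and the mm10 genome are named in the submitters' processing notes; the counting tool, its strand setting and the gene annotation were not given in the sources used here. The table holds 22618 genes, 14 of them with a total of 0, and no row without a gene name. Of the gene identifiers, 22054 matched GENCODE M21 on GRCm38 (mm10), which gave positions and gene types, and 564 did not. Genes without a match keep their deposited symbol and have no position.

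Each library's time point and replicate number came from its label, giving 6 groups of 2. Library totals were 34715506 to 46074052 counts, 95.2% to 96.1% of them in protein-coding genes. At the smallest library a count of 0 allows up to 0.0864 CPM (3 counts of the total), and at the largest 0.0651 CPM; such limits cover counting error only, since PCR copies are not independent molecules. The 2 libraries of every time point differed by more than sampling noise (chi-square per degree of freedom from 16.8 at ZT18 to 100.5 at ZT10), so none was counted as a repeat of another. Overlapping genes shared reads: Gm20425 had 1.00 times the count of Trf in each library, and 34 of 16148 genes with a mean count of at least 10 had 12 counts identical to those of another gene. Such genes, antisense partners and near-identical family members are uncertain.

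Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by time point with a minimum count of 10 and a minimum total of 15, glmQLFit and glmQLFTest), which left 17142 genes. The design, the tests, the gene lists and the rule for naming genes were set before the data were examined. A 6-group fit gave a test of all time differences, the contrast of night minus day, ZT14 minus ZT10 and ZT02 minus ZT22; a fit of 24 h cosine and sine terms gave the test of a daily rhythm with its range and peak time; and 12 h terms were tested beside the 24 h terms. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a contrast is the log2 fold change divided by the root of its F value. The SE and 95% interval of a range or peak time come from a least-squares fit to log2 CPM (prior count 2) with 9 residual degrees of freedom. A range is the ratio of fitted peak to fitted trough.

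The 37 gene lists had 631 entries, 612 of them in the table. Lists were tested for night minus day with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation; no camera call held with the estimated one. Members called in the 24 h test were counted against all tested genes with Fisher's exact test, two-sided and adjusted over the lists. Fisher's test counts genes as independent, so its p is too small for lists whose members vary together. Genes were named as follows: Cry1, Cry2 and the tested core clock genes; for the 24 h test the 15 largest ranges among called genes with a mean of at least 5 CPM and peaks within 4 h between replicates 1 and 2 fitted alone; for night minus day the 10 largest rises and 10 largest falls among called genes of at least 5 CPM with all 3 night means on one side of all 3 day means; for the steps the 5 largest rises and falls among called genes of at least 5 CPM with both libraries of one time above both of the other; and up to 4 called members of each list with the smallest adjusted p, or the 2 most abundant where none was called. For the 12 h test the 5 largest amplitudes would have been named. Genes named only by a clone, model or identifier were passed over for naming. Some genes that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

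Each test was checked on simulated counts drawn from the real means and library sizes with 200 changed genes. Genes were drawn independently, so shifts shared by many genes of a library were not simulated. For the test of any time difference, the simulated changes were 24 h cosines, so other shapes were not tried. False calls were 7 of 131 calls for the 24 h test, 12 of 181 for night minus day and 7 of 122 for ZT14 minus ZT10. They were 7 of 116 for ZT02 minus ZT22, 9 of 101 for any time difference and 9 of 129 for the 12 h test. For the 24 h test (16858 genes) 16.4% of genes with a 1.5-fold range, 71.6% with 2-fold and 98.5% with 4-fold were recovered. For night minus day (16859 genes) the shares were 65.7%, 88.1% and 100%; for ZT14 minus ZT10 (16879 genes) 10.4%, 65.7% and 97.0%; for ZT02 minus ZT22 (16872 genes) 4.48%, 65.7% and 93.9%; for any time difference (16879 genes) 2.99%, 43.3% and 92.4%; and for the 12 h test (16864 genes) 19.4%, 62.7% and 98.5%. Alternatives were DESeq2 1.42.0, RLE factors, total counts only, limma-voom, no low-count filter, a mean of at least 5 CPM, a replicate block, thinning to the smallest library, the 24 h terms beside the 12 h terms, a 2-group fit of night against day, and leaving out each library. Leaving aside a pair of ZT02 and ZT06 libraries was added after the data were seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. All labels were used as given.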

Results

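Liver RNA was profiled over 1 day in male mice that lack functional copies of Cry1 and Cry2, the genes of the cryptochromes, which repress CLOCK:BMAL1-driven transcription in the circadian clock. The mice were fed at night, were on the C57BL/6j background and had a conventional gut flora. Livers were sampled every 4 h at zeitgeber time (ZT) 2, 6, 10, 14, 18 and 22, with 2 libraries per time point and 12 in all. ZT12 is by convention the start of the dark phase, so ZT14, ZT18 and ZT22 are called night and the other time points day. The light schedule itself was not given in the sources used here. Wild-type libraries named in the design text belong to another series and were not analysed here, so every comparison is between times of day within the mutant. Total exon counts were between 34715506 (ZT06 replicate 2) and 46074052 (ZT02 replicate 1) per library over 22618 genes, of which 17142 were tested. Levels are given in CPM, counts scaled to a common library size after adjusting for library composition. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries.

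Reads remained at both targeted genes in every library. Cry1 (ENSMUSG00000020038, chromosome 10, 85131700 to 85185064, mm10) was at 8.72 ± 2.19 CPM (SD, n = 12) and Cry2 (ENSMUSG00000068742, chromosome 2, 92403646 to 92434043) at 17.7 ± 3.10 CPM. Their raw counts ranged from 202 to 544 for Cry1 and from 462 to 819 for Cry2. Gene counts do not show which exons the reads came from, so these levels neither check nor contradict the genotype label. Neither gene passed the 24 h test (edgeR quasi-likelihood, adjusted p = 0.121 for Cry1 and 0.0653 for Cry2). Cry2 was lower at night, at 15.3 ± 2.05 CPM (SD, n = 6) against 20.1 ± 1.81 by day (log2 difference -0.39, edgeR adjusted p = 0.0284), and Cry1 did not differ (adjusted p = 0.664).

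Most core clock genes had low-amplitude or undetected daily variation. Of 18 tested members of the list of core clock and clock-output transcription factors, 4 passed the 24 h test over all genes and 8 when adjusted over the list alone. Per2, a repressor of the clock (chromosome 1, 91415982 to 91459324), rose to 106 ± 19.9 CPM (SD, n = 2) at ZT14 from 54.7 ± 6.54 at ZT06, with a fitted peak-to-trough range of 1.80-fold (95% interval 1.37 to 2.36, edgeR adjusted p = 0.0121). Dbp, a clock-controlled transcription factor, had a range of 1.79-fold (1.45 to 2.21) and peaked at ZT 3.10 ± 0.61 h (SE), with adjusted p = 0.00566. Per3 had a range of 1.77-fold (1.44 to 2.18), peaking at ZT 2.25 ± 0.61 h, with adjusted p = 0.00596. Clock had a range of 1.41-fold and adjusted p = 0.0351, and its call was lost in 8 of the 12 fits that left out 1 library, all but those without ZT06 replicate 1, ZT10 replicate 1, ZT14 replicate 1 or ZT22 replicate 1 (adjusted p up to 0.191 over all alternatives). Arntl, which encodes BMAL1, had a fitted range of 1.36-fold with an approximate upper limit of 2.22 (adjusted p = 0.421). Nr1d1, which encodes REV-ERBα, had 1.28-fold (approximate upper limit 1.86, adjusted p = 0.383). Nr1d2 (1.78-fold, adjusted p = 0.0533), Nfil3 (1.56-fold, 0.0561), Hlf (1.28-fold, 0.0723), Bhlhe40 (1.64-fold, 0.114), Tef (1.20-fold, 0.115), Bhlhe41 (1.48-fold, 0.136) and Ciart, listed as Gm129 (1.46-fold, 0.241), did not pass. Rora (1.18-fold, adjusted p = 0.598), Per1 (1.24-fold, 0.711), Csnk1e (1.06-fold, 0.861) and Csnk1d (1.03-fold, 0.889) did not pass either. The share of called members, 22.2% against 12.0% of all genes, was not called different (Fisher's exact test, two-sided, adjusted p = 0.588). A list of 18 genes leaves a higher share open. The list was not called in 1 direction between night and day (camera, adjusted p = 0.259), with 1 member higher and 3 lower at night (edgeR; 2 and 5 adjusted over the list alone). Leaving aside ZT02 replicate 1 and ZT06 replicate 2 together ended the 24 h calls of Per2 and Clock. Leaving aside ZT02 replicate 2 and ZT06 replicate 1 also ended that of Clock. Both alternatives were chosen after seeing the data.

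**Figure D1:**
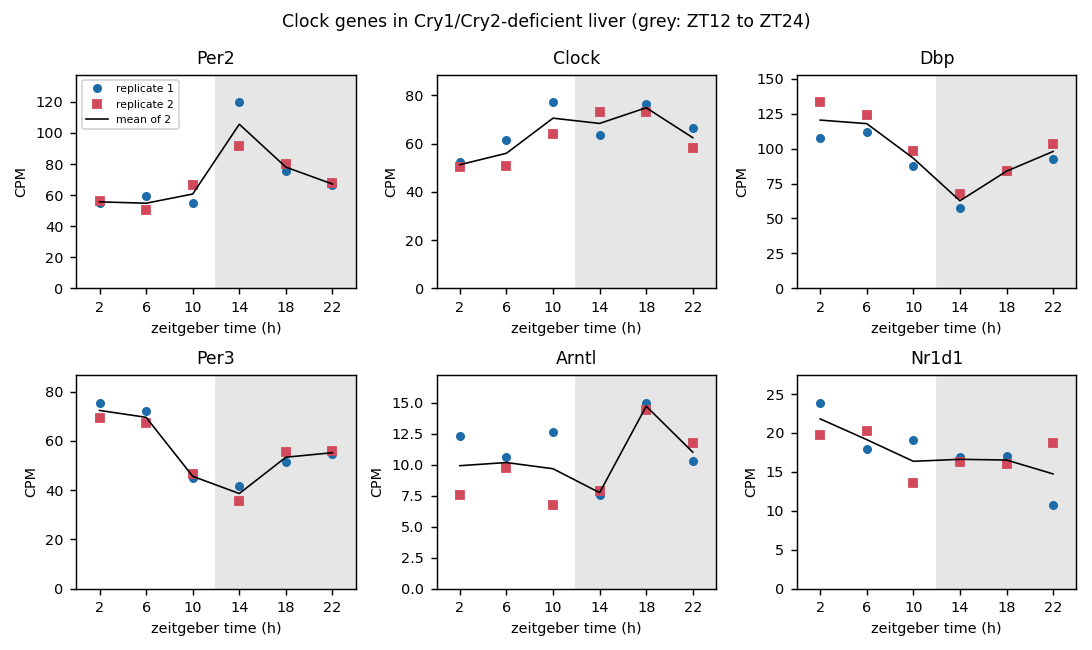
CPM (vertical axes, from 0) of 6 clock genes against zeitgeber time in hours; points are single libraries by replicate number and lines join the means of 2. Per2 reached 106 CPM at ZT14 and Per3 was lowest there at 38.6 CPM, while Arntl ranged from 7.74 CPM at ZT14 to 14.7 CPM at ZT18.

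Daily variation outside the clock list was widespread. The 24 h harmonic was called in 2051 of 17142 genes (12.0%), with a median range of 1.66-fold; 574 of them exceeded 2-fold and 116 exceeded 4-fold. Fitted peaks were most frequent at ZT12 to 16 (556 genes), ZT4 to 8 (447 genes) and ZT16 to 20 (396 genes). Heat shock protein genes had large ranges. Hspa1b, which encodes an inducible HSP70, was at 96.2 ± 13.8 CPM (SD, n = 2) at ZT14 and at 3.74 ± 2.12 at ZT22, a fitted range of 20.7-fold (95% interval 3.50 to 123, adjusted p = 0.0132). Hsph1 ranged 5.51-fold (adjusted p = 0.00247). The acute-phase genes Saa1 and Saa2 had ranges of 16.1-fold (2.85 to 91.2, adjusted p = 0.0172) and 18-fold (2.39 to 135, adjusted p = 0.0228), and were highest at ZT22, where Saa1 was at 155 and 316 CPM against at most 38.0 CPM in the other libraries. Saa1 and Saa2 are near-identical neighbours, so the split of reads between them is uncertain. Acot3, an acyl-CoA thioesterase gene, ranged 14.2-fold (5.90 to 34.4) with its peak at ZT 6.11 ± 0.59 h (SE), and Cyp4a14, a fatty acid hydroxylase gene, 7.46-fold. Rgs16, Nipal1 and Abcd2 also peaked by day, with ranges of 8.96-, 8.83- and 6.56-fold. Creld2 ranged 9.82-fold, Selenbp2 8.43-fold, Ugt2b38 7.33-fold and Slc16a6 5.06-fold, all peaking at night. Nocturnin, listed as Ccrn4l, ranged 7.81-fold with a peak at ZT 13.9, and Gbp10, an interferon-inducible GTPase gene, 5.79-fold with a peak at ZT 0.364. The test without any assumed shape called 826 genes, of which 657 were also called by the 24 h test.

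These counts depended on single libraries and on 4 libraries of ZT02 and ZT06. The 24 h count was 1256 without ZT02 replicate 1, 1251 without ZT10 replicate 2, 1201 without ZT14 replicate 2, and 1212 and 1240 without ZT18 replicates 1 and 2. The count over 6 time points was 511 without ZT02 replicate 2, 338 and 541 without ZT14 replicates 1 and 2, 174 and 184 without ZT18 replicates 1 and 2, and 363 and 486 without ZT22 replicates 1 and 2. The 9835 genes of at least 5 CPM outside the fatty acid and cholesterol synthesis lists were compared. Their log2 CPM was centred and scaled per gene over the 12 libraries. On this scale, ZT02 replicate 1 correlated with ZT06 replicate 1 (r = 0.48) more than with ZT02 replicate 2 (r = 0.16). ZT02 replicate 2 correlated with ZT06 replicate 2 (r = 0.49) more than ZT06 replicates 1 and 2 with each other (r = 0.07). Unscaled log2 counts correlated at r = 0.982 between the 2 libraries of ZT02 and of ZT06. Genes are not independent replicates, and no p is given. Without ZT02 replicate 2 and ZT06 replicate 1 the 24 h count was 1276, of which 1030 genes were shared, and without ZT02 replicate 1 and ZT06 replicate 2 it was 568, of which 534 were shared; these alternatives were chosen after seeing the data. Among single genes, the 24 h calls of Rgs16 and Abcd2 were lost in 8 and 9 of the 12 fits that left out 1 library (edgeR adjusted p up to 0.0898 and 0.10 over all alternatives). That of Saa2 was lost without ZT10 replicate 2 or ZT22 replicate 2 (up to 0.0826), that of Cyp4a14 without either ZT18 library (up to 0.0594) and that of Nipal1 without ZT14 replicate 2 or ZT18 replicate 2 (up to 0.0584). Leaving aside ZT02 replicate 2 and ZT06 replicate 1 ended the 24 h calls of Bhlha15, Bop1, Chac1, Clock, Dusp1, Ehhadh, G6pc, Gas5, Nop2, Oit3, Rgs16, Tsc22d3 and Ugt2b38. It also ended the ZT14 against ZT10 call of Pck1. Leaving aside ZT02 replicate 1 and ZT06 replicate 2 ended all of these except that of Chac1. The 24 h calls of Abcd2, Abcg5, Acot1, Ccnd1, Ccrn4l, Cd36, Dmbt1, Mcm2, Mcm5, Mvk, Nipal1, Nr1i3, Orm1, Per2, Ppp1r3b, Saa2, Stat2 and Trib3 were lost as well. So were the night and day calls of Abcd2 and Mup21.

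**Figure D2:**
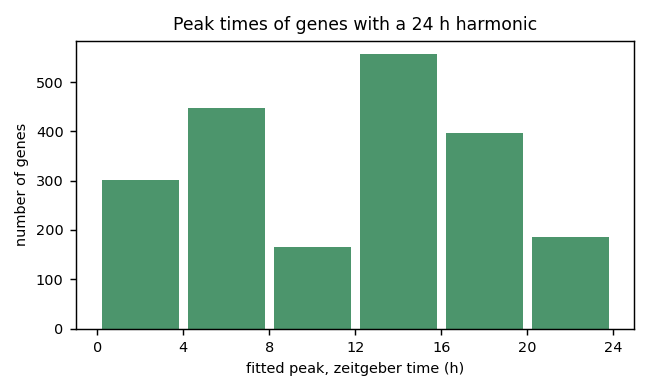
Number of genes (vertical axis, from 0) by fitted peak time in 4 h bins of zeitgeber time (horizontal axis, h), for the 2051 genes called in the 24 h test. The bins hold between 165 genes (ZT8 to 12) and 556 genes (ZT12 to 16).

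Night was then set against day, since the mice fed at night. The contrast was called in 1662 genes, 823 higher and 839 lower at night; with scaling by total counts alone the split was 1077 higher and 624 lower. Creld2, which encodes an ER-resident protein induced by unfolded proteins (chromosome 15, 88819646 to 88826683), was at 104 ± 52.5 CPM (SD, n = 6) at night and 20.8 ± 4.86 by day, a log2 difference of 2.16 ± 0.16 (SE, edgeR adjusted p = 0.000374). Selenbp2 and Ugt2b38 were 4.06- and 3.76-fold higher at night. Mvd, of the mevalonate pathway, was 2.87-fold higher, and Serpina12, which encodes the secreted protein vaspin, 2.70-fold. Sdf2l1 (2.67-fold), Hspb1 (2.57-fold), Slc16a6 (2.44-fold) and Mup21, a major urinary protein gene (2.43-fold), completed the named rises. Mup21 belongs to a family of near-identical copies, so its counts are uncertain, and its call was lost in 9 of the 12 fits without 1 library; that of Mvd was lost in 8 (adjusted p up to 0.125 and 0.0901 over all alternatives). Igfbp1, a fasting-induced binding protein gene, had the largest fall at night among the called genes of at least 5 CPM that the naming rule takes, at 11.0 ± 8.39 CPM against 58.8 ± 44.5 by day (log2 difference -2.61 ± 0.54, adjusted p = 0.0156). Acot3 fell by 2.59 ± 0.32 on the log2 scale, Nipal1 by 2.17, Abcd2 by 1.91 and Cyp4a14 by 1.90. Irs2, the insulin receptor substrate, was at 7.70 ± 1.96 CPM at night and 22.4 ± 4.81 by day (adjusted p = 0.000512). Gpcpd1, Smad9, Tcp11l2 and Cyp2c38 fell by 1.51, 1.48, 1.47 and 1.41 on the log2 scale. The call of Igfbp1 was lost without ZT18 replicate 2 or ZT22 replicate 1, and that of Abcd2 without ZT14 replicate 1, either ZT18 library or ZT22 replicate 1 (edgeR adjusted p up to 0.0548 and 0.0731 over all alternatives).

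The night and day count was 812 without ZT02 replicate 2, 1032 without ZT06 replicate 2, 697 without ZT14 replicate 1, 611 and 664 without ZT18 replicates 1 and 2, and 781 and 835 without ZT22 replicates 1 and 2. It was 865 without ZT02 replicate 2 and ZT06 replicate 1 together and 1107 without ZT02 replicate 1 and ZT06 replicate 2, of which 767 and 921 genes were shared with the fit of all 12 libraries.

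**Figure D3:**
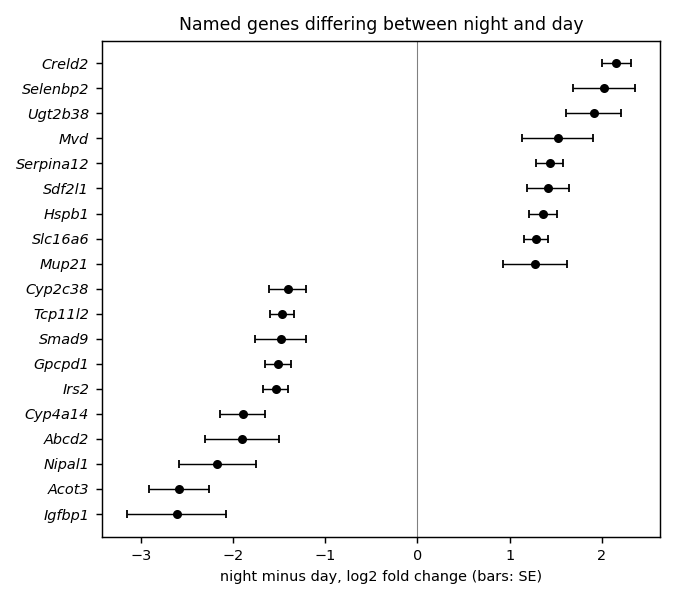
Log2 fold change, night minus day (horizontal axis; points are edgeR estimates and bars their SE), for 9 named rises and 10 named falls. The estimates run from -2.61 for Igfbp1 to 2.16 for Creld2.

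Most heat shock and ER chaperone genes tested were called higher over the 3 night time points, with list means highest at ZT14. Of 16 heat shock factor targets, 15 passed the 24 h test (15 adjusted over the list alone), and 13 were higher and none lower at night. The rise of this list was not held through the night. Its mean centred log2 CPM was 1.10 and 0.999 in the libraries of ZT14, 0.25 and 0.36 at ZT18, and -0.07 and -0.33 at ZT22, within the day range of -0.89 to 0.03. Hspb1 was at 42.2 ± 14.4 CPM (SD, n = 6) at night and 15.8 ± 4.23 by day, Ahsa1 at 90.9 ± 14.1 and 61.1 ± 4.85, and Stip1 at 113 ± 28.6 and 60.2 ± 10.7. The list was called by camera (adjusted p = 8.4e-11; adjusted p = 0.407 with an estimated correlation), and its called members were more frequent than among all genes (Fisher's exact test, adjusted p = 7.2e-12). Of 22 genes of ER chaperones and the unfolded protein response, 15 passed the 24 h test (17 adjusted over the list alone) and 13 were higher at night, with none lower. This list stood at 0.37 and 0.68 at ZT14, 0.22 and 0.48 at ZT18, and 0.08 and 0.19 at ZT22, against -0.67 to 0.05 by day. Syvn1, an ER ubiquitin ligase gene, ranged 3.95-fold, Hyou1 3.73-fold and Manf 3.22-fold. Hspa5, which encodes the chaperone BiP and was chosen after its values were seen, ranged 3.22-fold (95% interval 1.96 to 5.29, edgeR adjusted p = 0.0069). Camera called this list with adjusted p = 1.7e-09 (adjusted p = 0.49 with an estimated correlation), and Fisher's exact test gave adjusted p = 1.9e-08. Pancreatic acinar transcripts were present in 1 of the libraries in which these genes were highest, ZT14 replicate 2, at a sum of 14.2 CPM over 6 genes, against 0.107 in ZT14 replicate 1. Immediate-early genes stood at 0.41 (mean centred log2 CPM) in ZT14 replicate 1, above the other night libraries, and at 0.38 in the day library ZT10 replicate 1. In ZT14 replicates 1 and 2, lymphocyte markers were the lowest of all 12 libraries (-0.97 and -0.71) and erythroid markers stood at 0.96 and 0.71. In ribosome biogenesis, 11 of 25 genes passed the 24 h test (17 adjusted over the list alone; Fisher's exact test, adjusted p = 0.000752), among them Nolc1 (2.35-fold, peak at ZT 14.3), Nop56 (2.14-fold), Nop2 (2.02-fold) and Bop1 (1.40-fold). At night 3 were higher (camera adjusted p = 0.0371, and 0.787 with an estimated correlation). The camera call was lost without ZT02 replicate 2, ZT06 replicate 1, ZT10 replicate 1 or ZT22 replicate 2. The list stood at 0.36 and 0.34 at ZT14, -0.09 and -0.11 at ZT18, and -0.14 and 0.05 at ZT22. Day libraries ran from -0.30 to 0.45, the highest in ZT10 replicate 2. None of 74 cytosolic ribosomal protein genes passed the 24 h test (0 adjusted over the list alone), with Rpl4 at 1.06-fold and Rps2 at 1.01-fold. This was fewer than among all genes (Fisher's exact test, adjusted p = 0.00134). The estimated inter-gene correlation was 0.45 for heat shock factor targets, 0.53 for ER chaperones, 0.46 for ribosome biogenesis and 0.71 for ribosomal proteins. Fisher's test takes genes as independent, so its p-values for these lists are too small. The 74 genes as a set were called higher by camera at a median of 0.06 on the log2 scale (adjusted p = 0.0381; adjusted p = 0.876 with an estimated correlation), a call lost without ZT02 replicate 1, ZT06 replicate 1, ZT10 replicate 1, ZT14 replicate 1, ZT18 replicate 1 or ZT22 replicate 2.

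Some genes of fatty acid oxidation and fasting metabolism were lower at night, and none was called higher. Of 26 fatty acid oxidation genes and targets of PPARα, 7 passed the 24 h test (8 adjusted over the list alone), and 9 were lower and none higher at night. Acot1 was at 24.7 ± 4.23 CPM (SD, n = 6) at night and 52.0 ± 13.1 by day, Ehhadh at 281 ± 38.3 and 448 ± 66.6, and Cd36, a fatty acid transporter gene, at 29.2 ± 4.01 and 43.2 ± 6.86. Camera gave adjusted p = 6.9e-07 (adjusted p = 0.49 with an estimated correlation). Of 15 genes of gluconeogenesis and the fasting response, 2 passed the 24 h test (4 adjusted over the list alone), Irs2 with 4.68-fold and G6pc, the glucose-6-phosphatase gene, with 2.31-fold, and 6 were lower at night (camera adjusted p = 0.000982; adjusted p = 0.49 with an estimated correlation). The call of G6pc was lost in every fit without 1 library except those without ZT10 replicate 2 or ZT18 replicate 2 (edgeR adjusted p up to 0.134 over all alternatives), and that of Cd36 without ZT06 replicate 2, ZT18 replicate 2 or ZT22 replicate 1 (up to 0.122). In autophagy and lysosome, 4 of 16 passed (7 adjusted over the list alone), including Gabarapl1 (2.29-fold) and Bnip3 (1.80-fold), and 6 were lower at night (camera adjusted p = 0.000935; adjusted p = 0.37 with an estimated correlation). In bile acid synthesis and transport, 5 of 17 passed (6 adjusted over the list alone) and 3 were lower at night (camera adjusted p = 0.014; adjusted p = 0.37 with an estimated correlation). Abcg8 and Abcg5, whose products export sterols, ranged 2.42- and 1.95-fold with peaks at ZT 4.81 and 5.71; the call of Abcg5 was lost without either ZT18 library (edgeR adjusted p up to 0.0933 over all alternatives). In xenobiotic metabolism, 3 of 20 passed (6 adjusted over the list alone) and 4 were lower at night, with Nr1i3, which encodes the receptor CAR, at 2.23-fold, Sult1d1 at 1.89-fold and Por at 1.79-fold (camera adjusted p = 0.00893; adjusted p = 0.528 with an estimated correlation; lost without ZT06 replicate 1). The share of members called in the 24 h test ran from 13.3% for gluconeogenesis to 29.4% for bile acids, against 12.0% of all genes. None of these shares was called different, and a higher share is left open. Fisher's exact test gave adjusted p = 0.117 for fatty acid oxidation, 0.842 for gluconeogenesis and 0.296 for autophagy. It gave 0.144 for bile acids and 0.842 for xenobiotic metabolism.

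Fatty acid and cholesterol synthesis genes differed between the libraries of a time point at ZT02, ZT06 and ZT10, and less at the night time points. Of 18 fatty acid synthesis genes, 1 passed the 24 h test (1 adjusted over the list alone), and the list did not pass the night and day test (camera adjusted p = 0.105). Averaged over the 18 genes, replicate 1 exceeded replicate 2 by 1.60 ± 0.28 on the log2 scale (SE over genes) at ZT02 and by 1.74 ± 0.24 at ZT06, while at ZT10 the difference was -1.01 ± 0.16. It was 0.56 ± 0.17 at ZT14, 0.34 ± 0.13 at ZT18 and 0.09 ± 0.09 at ZT22. Genes of a list are not independent, so an SE over genes does not measure the spread between libraries. Fasn, the fatty acid synthase gene, chosen after its values were seen, was at 1524 and 268 CPM in the 2 libraries of ZT02 and at 1898 and 273 CPM in those of ZT06. Of 24 genes of cholesterol synthesis and uptake, 1 passed the 24 h test (0 adjusted over the list alone), Mvk at 2.75-fold, a call lost in every fit without 1 library except those without ZT02 replicate 2 or ZT06 replicate 1, and 2 were higher at night (camera adjusted p = 0.00025; adjusted p = 0.728 with an estimated correlation). Replicate 1 exceeded replicate 2 by 1.44 ± 0.16 at ZT02 and 0.93 ± 0.12 at ZT06 in this list. The differences were -0.76 ± 0.10 at ZT10, 0.19 ± 0.06 at ZT14, -0.15 ± 0.04 at ZT18 and -0.27 ± 0.04 at ZT22. Cholesterol genes were not higher throughout the night. Their mean centred log2 CPM was -0.03 and -0.22 at ZT14, 0.49 and 0.64 at ZT18, and 0.30 and 0.58 at ZT22. Day libraries ran from -1.27 in ZT10 replicate 1 to 0.63 in ZT02 replicate 1. Fisher's exact test of the members called in the 24 h test gave adjusted p = 0.842 for fatty acid synthesis and 0.688 for cholesterol.

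**Figure D4:**
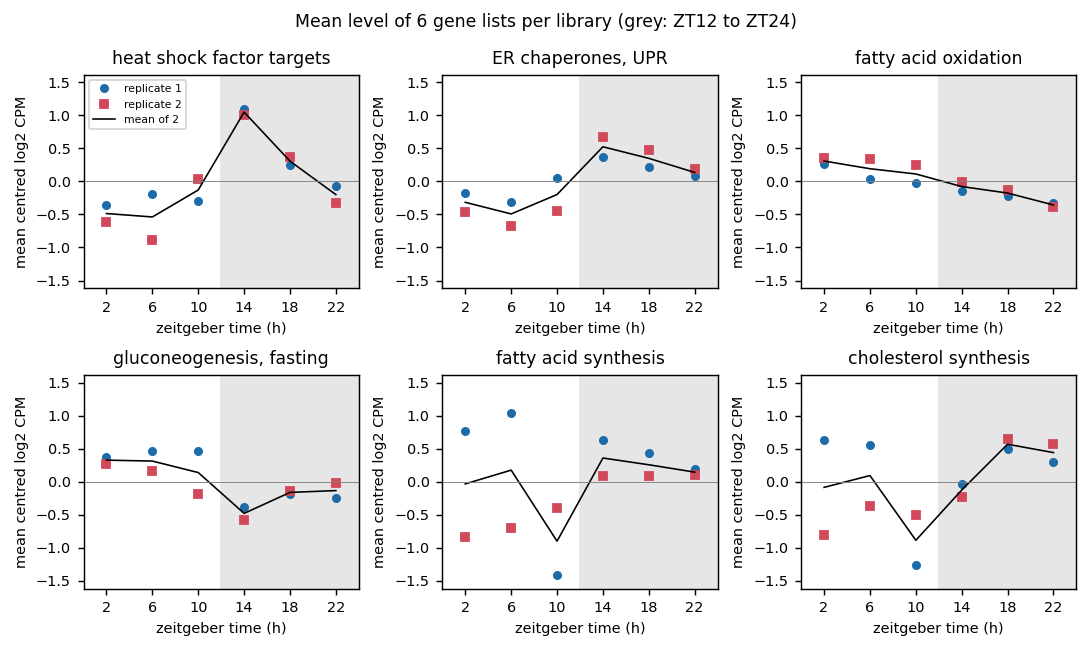
Mean centred log2 CPM (vertical axes, the same scale in each panel) of 6 gene lists against zeitgeber time in hours; points are single libraries by replicate number and lines join the means of 2. Heat shock factor targets reached 1.10 in ZT14 replicate 1, while fatty acid synthesis was at 0.76 and -0.83 in the 2 libraries of ZT02.

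The step from ZT10 to ZT14, across the start of the dark phase, was called in 211 genes, 124 higher and 87 lower at ZT14. Hspa1b rose by 3.14 ± 0.63 on the log2 scale (SE, edgeR adjusted p = 0.0428), Creld2 by 2.66 ± 0.29 (0.00524), Hapln4 by 1.90, Serpina12 by 1.71 and Actg1, a cytoplasmic actin gene, by 1.70. Tcp11l2 fell by 2.41 ± 0.24 (adjusted p = 0.00442), Pck1, the gluconeogenic PEP carboxykinase gene, by 2.33 ± 0.48 (0.0463), Lpin2 by 2.09, Bmf by 1.58 and Slc24a6 by 1.52. Of the heat shock factor targets 7 rose over this step, and of the ER chaperone list 3. In fits that left out 1 library, the count fell most without ZT14 replicate 1 or ZT10 replicate 1, and rose without ZT14 replicate 2. It also fell without any 1 library of ZT18 or ZT22. Those time points are not part of this contrast but share in its estimate of spread, so that fall does not show dependence on their levels. Of the 10 named genes, all but Tcp11l2 lost their call without ZT14 replicate 1, Pck1 lost it in 9 of the 12 such fits and Hspa1b in 7. Without ZT10 replicate 1 Hapln4, Serpina12, Actg1, Lpin2, Bmf and Slc24a6 lost it too.

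The step from ZT22 to ZT02 was called in 1 gene, Trib3, a stress-induced pseudokinase gene that lies below the expression limit for naming in this comparison and was named after its values were seen. It was 3.99-fold higher at ZT02 (log2 difference 2.00 ± 0.19 SE, edgeR adjusted p = 0.00948), at 8.49 CPM against 2.13 CPM. At an unadjusted p under 0.05, 1600 genes differed, and DESeq2 called 124. The count was 0 without ZT02 replicate 1, ZT02 replicate 2 or ZT22 replicate 1, and 33 without ZT22 replicate 2. No gene had a 12 h harmonic in edgeR, with 1358 genes at an unadjusted p under 0.05; DESeq2 called 35 and limma-voom 0.

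Some sex-biased and acute-phase genes passed the 24 h test. The shares were 28.6% of male-biased, 15.4% of female-biased and 33.3% of acute-phase genes, against 12.0% of all genes. None of these shares was called different (Fisher's exact test, adjusted p = 0.212, 0.842 and 0.068 in this order), and a higher share is left open. Of 14 male-biased liver genes, 4 passed the 24 h test (7 adjusted over the list alone), all 4 higher at night: Selenbp2, Ugt2b38, Cyp2u1 (2.06-fold) and Hsd3b5 (1.93-fold) (camera adjusted p = 8.4e-05; adjusted p = 0.49 with an estimated correlation). Of 13 female-biased genes, 2 passed (4 adjusted over the list alone), Acot3 and Abcd2, and 3 were lower at night. Camera gave adjusted p = 0.028 (adjusted p = 0.562 with an estimated correlation), a call lost without ZT02 replicate 1. The day library ZT10 replicate 1 went against both sex-biased lists, at -0.68 (mean centred log2 CPM) for female-biased and 0.31 for male-biased genes. The other day libraries ran from 0.28 to 1.18 for female-biased and from -0.80 to -0.28 for male-biased genes. Night libraries ran from -0.60 to -0.12 and from -0.0068 to 0.81 in this order. Of 18 acute-phase and complement genes, 6 passed (9 adjusted over the list alone) and 4 were higher at night, with Saa4 at 2.39-fold and Orm1 at 2.29-fold beside Saa1 and Saa2 (camera adjusted p = 0.00893; adjusted p = 0.728 with an estimated correlation; lost without ZT22 replicate 2). The acute-phase list was not higher throughout the night. Its mean centred log2 CPM was -0.26 and -0.61 in the libraries of ZT14, 0.15 and -0.06 at ZT18, and 0.72 and 1.32 at ZT22. Day libraries ran from -0.49 to 0.08. Neutrophil markers were higher at ZT22 by a median of 2.11-fold, at 0.99 CPM for S100a8, and lymphocyte markers by a median of 1.40-fold. Of 20 clock-driven liver outputs, 8 passed (12 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00827), among them Tsku (3.30-fold, peak at ZT 15.6), Upp2 (2.75-fold, peak at ZT 4.16) and Dtx4 (1.91-fold), with 2 higher and 4 lower at night (4 and 5 adjusted over the list alone) and no shared direction (camera adjusted p = 0.873, with a median log2 difference of 0.05 and a mean of 0.04 against a downward test direction). Both cold-inducible RNA-binding protein genes passed (2 adjusted over the list alone), Cirbp with 3.42-fold and a peak at ZT 4.48 and Rbm3 with 1.74-fold and a peak at ZT 11.2. In glycolysis and glycogen metabolism, 4 of 18 passed (5 adjusted over the list alone), including Ppp1r3b (2.15-fold, peak at ZT 16.2), which encodes a glycogen-targeting phosphatase subunit (camera adjusted p = 0.783, median 0.13 and mean -0.04); its call was lost without ZT06 replicate 2, either ZT14 library or ZT18 replicate 2 (edgeR adjusted p up to 0.121 over all alternatives). Of 12 amino acid response genes, 2 passed (6 adjusted over the list alone), Trib3 and Chac1 (camera adjusted p = 0.968, median 0.06 and mean -0.03); the call of Chac1 was lost in 5 of the 12 fits without 1 library, ZT02 replicate 2 and all ZT14 and ZT18 libraries. Of 13 glucocorticoid-responsive genes, 2 passed (3 adjusted over the list alone), Tsc22d3 (2.75-fold) and Dusp1 (3.01-fold), the latter lost in every fit without 1 library except those without a ZT10 library, the former without either ZT02 library, ZT06 replicate 2, ZT14 replicate 1 or ZT18 replicate 2 (camera adjusted p = 0.885, median 0.03 and mean -0.08). Growth hormone signalling (0 of 12; camera adjusted p = 0.241) and nuclear-encoded oxidative phosphorylation (0 of 26; 0.927, with a median of -0.0067 and a mean of 0.01) had no called member in the 24 h test (0 adjusted over the list alone), where 5407 of all genes had an unadjusted p under 0.05 and DESeq2 called 3378. Between night and day, 2 of the 12 growth hormone signalling genes were lower at night (3 adjusted over the list alone). Fisher's exact test gave adjusted p = 0.068 for the cold-inducible genes, 0.588 for glycolysis, 0.842 for the amino acid response and for glucocorticoid-responsive genes, 0.688 for growth hormone signalling and 0.197 for oxidative phosphorylation.

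Few markers of other cell types passed the 24 h test. None of 12 Kupffer cell (camera adjusted p = 0.136), 12 stellate cell and fibroblast (0.968, with a median of -0.0099 and a mean of 0.05), 7 bile duct cell (0.733), 3 neutrophil (0.602), 6 erythroid (0.103) or 3 pancreas and adipose markers (0.674) passed the 24 h test (edgeR; adjusted over the list alone 1 neutrophil marker passed, 0 of the others). Sinusoidal endothelial markers had 2 of 12 called, Lyve1 (2.30-fold) and Oit3 (1.32-fold, lost in 9 of the 12 fits without 1 library), or 3 adjusted over the list alone (camera adjusted p = 0.152). Of 14 lymphocyte markers, 1 passed, Cd8a, at a mean of 0.327 CPM (1 adjusted over the list alone), and camera called the list lower over the 3 night time points (adjusted p = 0.0398; adjusted p = 0.528 with an estimated correlation; lost without ZT02 replicate 1, ZT06 replicate 1, ZT10 replicate 2, ZT18 replicate 1 or ZT22 replicate 1). This was not a level held through the night. The mean centred log2 CPM of the list was -0.97 and -0.71 in the libraries of ZT14, -0.22 and 0.02 at ZT18, and 0.34 and 0.62 at ZT22. Neither the 10 periportal (camera adjusted p = 0.467) nor the 10 pericentral hepatocyte markers (0.369) had a called member (0 adjusted over the list alone). Among nuclear noncoding and RNA-quality genes 1 of 7 passed, Gas5 at 1.37-fold, which lost its call in 9 of the 12 fits without 1 library (camera adjusted p = 0.0843). Fisher's exact test gave adjusted p of 0.688 or more for each list of this paragraph. None of the 13 mitochondrially encoded genes was among the genes analysed.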

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

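All tests of explanations in this part were chosen after the values they explain were seen, except the prediction of library times, whose 6 h limit was set before its result was known; the criteria for the immediate-early and feeding tests were made stricter after a first run. Chance alone would flag about 1 in 20 groups, and 76 groups of 6 libraries (day or night, 35 lists and 3 library measures) gave 5 single libraries far from the other 5.

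The summed level of 6 pancreatic acinar genes in ZT14 replicate 2 was 14.2 CPM, with the next night library at 2.70 CPM. Immediate-early genes in ZT14 replicate 1 stood at 0.41 (mean centred log2 CPM) against -0.0043 in the next night library. The day library ZT10 replicate 1 was near it at 0.38. Interferon response genes in ZT02 replicate 1 stood at 0.71 against -0.10 in the next day library. Neutrophil markers in ZT10 replicate 2 were the lowest of the day libraries at -0.53, with the next at -0.06. Erythroid markers in ZT02 replicate 1 stood at 1.45 against -0.39 in the next day library.

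Fatty acid and cholesterol synthesis genes differed between the 2 libraries of ZT02 and of ZT06, which may reflect exchanged time labels or a condition shared by certain mice. A shift shared by all replicate 1 libraries is argued against, since at ZT10 the difference of replicate 1 minus replicate 2 was -1.01 on the log2 scale. The time predicted for the 4 libraries from genes outside these lists erred by at most 4.75 h, under the 6 h limit, but that limit was wrong: neighbouring labels are only 4 h apart, so it could not see an exchange between them, and it placed ZT02 replicates 1 and 2 at 0.75 and 5.50 h and ZT06 replicates 1 and 2 at 1.25 and 3.25 h, so that ZT06 replicate 2 also lay nearer ZT02. Exchanging the labels of ZT02 replicate 2 and ZT06 replicate 1 lowered the share of the spread of 9835 other genes within time points from 37.6% to 31.5%. Of the 30 groupings that exchange 2 libraries it was the only one below the labels as given (the next was 38.2%). Exchanging ZT02 replicate 1 with ZT06 replicate 2 gives the same grouping. The correlations between these libraries were taken over the same genes, so this share is not separate evidence of an exchange. A condition shared by the replicate 1 mice of ZT02 and ZT06, such as more recent feeding, cannot be told apart from exchanged labels. Fasting genes were higher in them by 0.21 ± 0.09 (SE over 15 genes) while fatty acid oxidation genes differed by -0.20 ± 0.07. An SE over genes does not measure the spread between libraries, so these values do not decide. No label names a cage, batch or meal, and the labels were used as given.

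Heat shock and ER chaperone genes were highest at ZT14. Pancreatic acinar cells in the ZT14 and ZT18 samples are argued against for 3 libraries, since the lowest ER chaperone level of ZT14 replicate 1 and the ZT18 libraries lay 0.16 above the highest day library on the log2 scale while their acinar levels were at most 0.263 CPM. In ZT14 replicate 2 the acinar sum of 14.2 CPM was 0.684% of the ER chaperone excess over ZT14 replicate 1 (2072 CPM), far below what acinar cells would bring with it. Stress during tissue collection could not be excluded. Immediate-early genes were 0.24 ± 0.18 higher at ZT14 (SE over 16 genes), but an SE over genes does not measure the spread between libraries. The list stood at 0.41 and -0.0076 (mean centred log2 CPM) in ZT14 replicates 1 and 2, too far apart to decide. An effect of the time of day or of the night meal, which the design confounds, remains open and untested.

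Saa1 and Saa2 were highest at ZT22. A larger number of white blood cells as the only source of the rise is argued against. Of 29 markers of neutrophils, lymphocytes and Kupffer cells, none was over 3.31-fold higher in a ZT22 library than the average of other times. Saa1 was 9.94-fold higher in the lower ZT22 library. These markers were read as measures of cell number, so a higher Saa1 level per white cell was not tested. White cell markers were still higher at ZT22, by a median of 2.11-fold for neutrophils (3 genes of 0.496 to 1.66 CPM) and 1.40-fold for lymphocytes, and by 1.07-fold for Kupffer cells. Inflammation in the ZT22 mice unrelated to the time of day cannot be told apart from a time effect: the lower ZT22 library had 4.07 times the Saa1 level of the highest other library, as either would give, and there were only 2 libraries.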

How the results depend on the processing

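The alternatives that leave aside 2 libraries of ZT02 and ZT06 were chosen after seeing the data, as were the tests of other assignments of the libraries; all others were planned. No result reversed direction. Chance is argued against for the main counts: among 100 assignments of the libraries to time points, the real one included, 1 reached the real count in each test. The counts were 826 genes against at most 58 in the others for any time difference, 2051 against 1 for the 24 h test and 1662 against 38 for night minus day. These assignments cannot tell the time of day from another condition shared by the libraries of a time point. DESeq2 called 2524 genes for any time difference, 3378 for the 24 h test, 35 for the 12 h test, 707 for ZT14 minus ZT10 (375 higher, 332 lower) and 124 for ZT02 minus ZT22; the cause was not tested. A mean of at least 5 CPM gave 338 for ZT14 minus ZT10 (196 higher, 142 lower) and 0 for ZT02 minus ZT22, where it removed Trib3 before testing. For ZT02 minus ZT22, total counts only gave 4, limma-voom 7 and no filter 7; the cause was not tested. The 2-group fit gave 938 for night minus day (420 higher, 518 lower), since it counts differences between night or day time points as spread. Camera with an estimated correlation called 0 lists against 15. Leaving aside ZT02 replicate 2 and ZT06 replicate 1 gave 1276 genes in the 24 h test, 865 for night minus day (492 higher, 373 lower), 199 higher for ZT14 minus ZT10 and 0 for ZT02 minus ZT22; leaving aside ZT02 replicate 1 and ZT06 replicate 2 gave 568, 1107 (523 lower), 199 and 25; fewer libraries were fitted, and the cause was not tested further. Leaving out 1 library gave 174 to 897 genes for any time difference, 1201 to 2225 for the 24 h test, 0 to 1 for the 12 h test, 611 to 1818 for night minus day (324 to 804 higher, 287 to 1014 lower), 3 to 391 for ZT14 minus ZT10 (1 to 166 higher, 2 to 225 lower), 0 to 33 for ZT02 minus ZT22 and 12 to 17 lists; a lone library of a time point is then assumed to vary like the others. The replicate numbers were not found to pair the samples across all time points (correlations of deviations over 15 pairs of time points from -0.23 to 0.43, 4 over 0.1). Libraries of ZT02 and ZT06 with the same replicate number did resemble each other in log2 CPM centred and scaled per gene (r = 0.48 for replicate 1 and 0.49 for replicate 2). With the replicate block the counts were 774, 1896, 1, 1609, 215 and 1 in the order of the tests above. Thinning to the smallest library, too small a change in depth to show whether depth limits the counts, gave 795, 1995, 0, 1589, 233 and 1.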

Other observations

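No test in this part was planned as a test of an explanation, and the genes of its last paragraph were chosen after their values were seen. Interferon response genes varied through the day. Of 19 genes, 9 passed the 24 h test (16 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00133), and 3 were higher at night (camera adjusted p = 0.0884). The estimated inter-gene correlation of this list was 0.55, so its Fisher p is too small. Ifit1 ranged 3.17-fold with a peak at ZT 21.5, Isg15 3.42-fold, Ifit3 2.51-fold and Stat2 1.65-fold with a peak at ZT 17.7. ZT02 replicate 1 stood apart from the other day libraries for this list at 0.71 (mean centred log2 CPM), and ZT22 replicate 2 was next at 0.50. In these 2 libraries Kupffer cell markers (0.42 and 0.27) and lymphocyte markers (0.53 and 0.62) were also the highest of the 12, and erythroid markers were highest in ZT02 replicate 1 (1.45). Of 20 cell cycle genes, 3 passed the 24 h test (3 adjusted over the list alone; Fisher's exact test, adjusted p = 0.842), Ccnd1 (1.88-fold, peak at ZT 20.7), Mcm5 (3.11-fold) and Mcm2 (2.33-fold), and the list was higher at night (camera adjusted p = 0.028; adjusted p = 0.728 with an estimated correlation), a call lost without ZT02 replicate 2, ZT06 replicate 2, ZT10 replicate 1, ZT14 replicate 2, ZT18 replicate 2 or ZT22 replicate 2. Cell cycle genes were not higher throughout the night. Their mean centred log2 CPM was -0.24 and 0.04 at ZT14, 0.27 and 0.53 at ZT18, and 0.07 and 0.31 at ZT22. Day libraries ran from -0.58 to 0.40, the highest in ZT02 replicate 1. The calls of Mcm5 and Mcm2 were lost in 5 and 7 of the 12 fits without 1 library (edgeR adjusted p up to 0.0833 and 0.098 over all alternatives). Of 16 immediate-early genes, 5 passed (7 adjusted over the list alone; Fisher's exact test, adjusted p = 0.124; camera adjusted p = 0.873); Jun peaked at ZT 13.4 with 3.17-fold, while Egr1 peaked at ZT 1.19 with 13.8-fold, at 28.9 and 6.32 CPM in the 2 libraries of ZT02.

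Some genes outside the naming rule stood out after their values were seen. Dmbt1 was at 394 CPM in ZT22 replicate 1 and at 0.026 CPM in ZT22 replicate 2, with at most 2.14 CPM in the other libraries, so its 24 h call rests on that library and was lost without it. Bhlha15, a transcription factor gene of secretory cells, was at 4.62 and 2.52 CPM at ZT14 and at most 0.513 CPM elsewhere. Lcn2, an acute-phase gene, was at 10.4 and 37.4 CPM at ZT22, with 11.8 CPM in ZT06 replicate 2. Ppp1r3g, a glycogen-targeting subunit gene, was at 3.64 ± 1.33 CPM (SD, n = 6) by day and 0.287 ± 0.128 at night, the night levels being 0.0764 of the day levels in the edgeR fit (adjusted p = 0.000753).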
